A study of Mus musculus with 12 samples.

How the data were processed

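The series measured RNA in mouse prostate of 4 genotypes: wild type, Hi-Myc, Pten knockout (labelled Ptenf/f) and the combination of both lesions (Hi-Myc/Ptenf/f, here Hi-Myc/Pten KO). Per the labels, bulk RNA-seq was made from viable cells positive for EPCAM, an epithelial surface protein, sorted from digested prostate, with 2 libraries per genotype and 8 in all. Single-cell RNA-seq was made from viable cells of the whole digested gland with 10x Genomics 3' chemistry, with 1 library per genotype and 4 in all. Every sample took its group from the genotype in its label. The wild-type samples are titled Scr, a name not explained here, and their genotype label is WT. The labels do not say that the 2 bulk libraries of a genotype came from separate animals, so p-values measure only the spread between these samples, which can be technical.

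The bulk values are expected counts per gene as deposited, made by the authors with the expectation-maximisation quantification of Partek, per the submitters' processing notes and the file headers. The aligner, the annotation release and the tool versions are not given in the sources used here. Of the deposited expected counts, 60.3% were not whole and 74.6% lay within 0.01 of a whole number, and all were rounded before testing. The genome build was mm10 per the submitters' processing notes. Of 20509 Ensembl gene IDs, 20456 were matched to a symbol and to mm10 coordinates in GENCODE release M 21, an annotation chosen here and not named by the authors. The single-cell values are expected counts of molecules (UMIs) per gene and cell as deposited, in which the authors split a molecule that fitted several genes into fractions, as seen in the values. The processing notes name Cell Ranger, Partek and Seurat with no version or role. The table held 25884 cells and 32308 gene columns, and columns without a gene name took 0.000161% of the counts and were left out. The authors' cell labels in the same table were used, and 10 of its label columns were not used. The filter the authors applied to cells is not given in the sources used here.

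Bulk counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, which is two-sided, in 1 fit over all 8 libraries with a mean per genotype, so that the 4 genotypes shared the 4 residual degrees of freedom. Genes were filtered with filterByExpr by genotype, which left 16538 genes, and scaled by TMM. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg within each comparison). The 6 comparisons were each single lesion and the combination against wild type, the combination against each single lesion, and the interaction, which is the Hi-Myc effect on the Pten KO background minus that on the wild-type background. Log2 fold changes are those of the fit, at the default prior count of edgeR. The SE beside them is the absolute log2 fold change divided by the square root of the test's F statistic. It was not estimated by the fit itself and is unreliable for genes near 0 counts in a genotype. The log2 counts-per-million (CPM) behind the list tests and the correlations between libraries had a prior count of 2. Levels are mean CPM of the 2 libraries with the SD. A fold against a genotype with 0 counts was computed against a floor of 3 counts over the group, and intervals and floors cover counting error only. With 1 to 3 counts the ratio is given with an exact 95% counting interval. On simulated counts with 200 changed genes, the test of the combination against wild type recovered 54.0% of 4-fold changes and 2.02% of 2-fold changes among 16096 genes, that of Hi-Myc 49.5% and 2.00% among 16130 genes, that of Pten KO 45.0% and 1.00% among 16109 genes, and that of the interaction 9.00% of 4-fold changes among 16096 genes.

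Before the data were examined, 28 gene lists, the cell type markers, the tests and the rule for named genes were fixed. One list holds the targeted genes Pten and Myc, and the other 27 were tested. They cover androgen-regulated luminal secretion, luminal progenitor or proximal cells, basal cells, seminal vesicle secretion, leukocytes, fibroblasts and smooth muscle, endothelium, erythrocytes, cell cycle, ribosome biogenesis and other MYC targets, FOXO targets and insulin feedback, senescence and its secreted factors, p53 targets, chemokines and cytokines, the interferon response, MHC class I and class II presentation, immune checkpoints and suppression, epithelial-mesenchymal transition (EMT), neuroendocrine genes, glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, polyamine and one-carbon metabolism, the unfolded protein response, immediate early genes and mitochondrially encoded genes. Each list was set against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated per list, and p-values were adjusted over the 27 lists. Of the lists of other cell types, 8 of 20 leukocyte, 3 of 15 fibroblast and smooth muscle, 0 of 10 endothelial, 3 of 5 erythrocyte, 6 of 11 seminal vesicle and 9 of 15 basal genes had at least 10 CPM in wild-type single cells labelled epithelial, and 1 gene each of the fibroblast and basal lists is in another list.

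The rule for named genes took, in each comparison against wild type, the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher genotype and every library of 1 genotype above every library of the other. It took 6 and 6 for the comparisons with a single lesion and for the interaction, where the separation was not required. Predicted genes and immunoglobulin or T cell receptor segments were left out. Of each list it took up to 4 members, called ones first by size of change and otherwise those with the highest CPM, and Pten, Myc and Ar were always included. In single cells it took the 5 highest and 5 lowest ratios among genes with at least 100 molecules and 100 CPM and an interval excluding 1, leaving out mitochondrial, ribosomal-protein, haemoglobin and Y-linked genes and Xist, plus the members of the senescence list. Classes with under 50 cells in either library were not compared. Genes that share reads with a near-identical copy, among the named ones Hspa1a with Hspa1b and Sbp with Sbpl, and the copies Svs3a and Svs3b or Hba-a1 and Hba-a2 within lists, have uncertain values.

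Single-cell classes came from the authors' labels for epithelial cells, T cells, macrophages, dendritic cells and cells labelled MDSC (myeloid-derived suppressor cells). For the other classes, among them endothelial and NK cells although labels for these also existed, cells with at least 200 detected genes were clustered with Leiden at resolution 1 (leidenalg 0.10.2 on igraph 0.11.9, Python 3.11.15, 2000 variable genes, 40 principal components, 20 neighbours, counts scaled to 10000 per cell). The automatic threshold of Scrublet marked almost no cells, so, once that was seen, a neighbour-based score against simulated doublets, at 0.8% expected doublets per 1000 cells, marked 1393 cells (5.50%), which were removed. A cluster was named from 24 fixed marker sets when at least 3 markers lay 2-fold or more above the other cells at 20 CPM or more, and it stayed unnamed when another set had more members among its 10 leading genes. Broader families, such as that of mononuclear phagocytes, were formed after the clusters were seen and can take in unnamed clusters. The authors' labelled cells were used whole, doublets included. The 4 libraries kept 5492, 3843, 8492 and 6092 cells for wild type, Hi-Myc, Pten KO and Hi-Myc/Pten KO, with median counts of 2812.75, 4090.5, 2480.265 and 2158.75 per cell. With 1 library per genotype there is no test between genotypes in single cells: levels are summed counts as CPM, ratios have exact Poisson intervals and shares exact Clopper-Pearson intervals, all covering counting error only. Shares of cells with a molecule were also given after thinning each cell to 500 counts. A list's median log2 ratio was placed among 10000 random lists matched on expression. On simulated counts for 16385 genes, 95.9% of the ratio intervals held the true value.

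Alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, library totals, a mean of at least 5 CPM or no filter on low counts, the replicate number as a block, leaving out each library in turn (a lone library left in a genotype is assumed to vary like the others), an adjusted p under 0.01, a log2 fold change of at least 1, fits of the 4 libraries compared, estimated correlations, fry, at least 500 detected genes per cell, Leiden resolutions of 0.5 and 2, doublets kept, and means over cells. Covariates for the seminal vesicle list, 5 fibroblast genes and the whole fibroblast list, counts not rounded, shares from the authors' labels and doublets removed from the authors' labelled cells were added after the data were seen.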

Results

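RNA was measured in sorted epithelial cells (8 bulk libraries, 2 per genotype) and in single cells of the whole gland (4 libraries, 1 per genotype) from mouse prostates that were wild type, carried the Hi-Myc transgene, lacked Pten, or had both lesions. Hi-Myc mice express human MYC from a prostate promoter, and Pten encodes a lipid phosphatase that restrains PI3K signalling. The bulk libraries held 10290664 and 9471704 counts in wild type and 6255119 and 4165169 in Hi-Myc. Those of Pten KO held 11379800 and 9362612, and those of Hi-Myc/Pten KO 7772972 and 8758814. Across genes, which are not independent, the replicates of a genotype had a Spearman coefficient of 0.9406 (Hi-Myc/Pten KO) to 0.9776 (Pten KO). Their chi-square per degree of freedom, which also grows with depth, was 50.21 in wild type and 24.63 in Hi-Myc. It was 45.48 in Pten KO and 131.7 in Hi-Myc/Pten KO. The fit shares its estimate of spread across genotypes, so calls in a comparison also rest on genotypes outside it. Transcripts of seminal vesicle secretion took 12.3% of the counts in Hi-Myc/Pten KO replicate 1 and 0.261% in replicate 2. They took 6.12% and 8.10% in wild type, 5.64% and 5.20% in Hi-Myc and 1.21% and 4.82% in Pten KO. Haemoglobin took at most 2.16% (Hi-Myc replicate 2) and at least 0.000703% (Pten KO replicate 1).

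Pten (ENSMUSG00000013663, mm10 chromosome 19, 32757497 to 32826160) had a mean of 116 ± 15.2 CPM (SD, n = 2) in wild type, 142 ± 8.47 in Hi-Myc, 106 ± 3.84 in Pten KO and 135 ± 34.9 in Hi-Myc/Pten KO. Its log2 change to wild type was -0.14 ± 0.22 (SE) in Pten KO (adjusted p = 0.948) and 0.22 ± 0.22 in Hi-Myc/Pten KO (adjusted p = 0.475). A count over the whole gene cannot show whether exons were deleted, so these values neither check nor contradict the labels. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374) had 203 ± 53.1 CPM in wild type, 113 ± 4.69 in Hi-Myc, 148 ± 6.62 in Pten KO and 47.5 ± 10.0 in Hi-Myc/Pten KO, and fell by 2.09 ± 0.25 on the log2 scale in Hi-Myc/Pten KO against wild type (adjusted p = 0.00349). These are counts of the mouse gene, and whether any reads of the human transgene entered them is not known. Ar, the androgen receptor (chromosome X, 98148769 to 98323215), had 128 ± 1.69, 127 ± 17.3, 149 ± 4.16 and 107 ± 41.2 CPM in the same order and was called in no comparison. In single cells that the authors labelled epithelial, Pten had 87.4 CPM in wild type, 122 in Hi-Myc, 81.9 in Pten KO and 118 in Hi-Myc/Pten KO. Myc in those cells had 29.0, 205, 23.3 and 256 CPM, 7.06 times the wild-type level in Hi-Myc (interval 6.49 to 7.69) and 8.83 times in Hi-Myc/Pten KO (8.16 to 9.56), the opposite direction to the bulk gene.

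**Figure D1:**
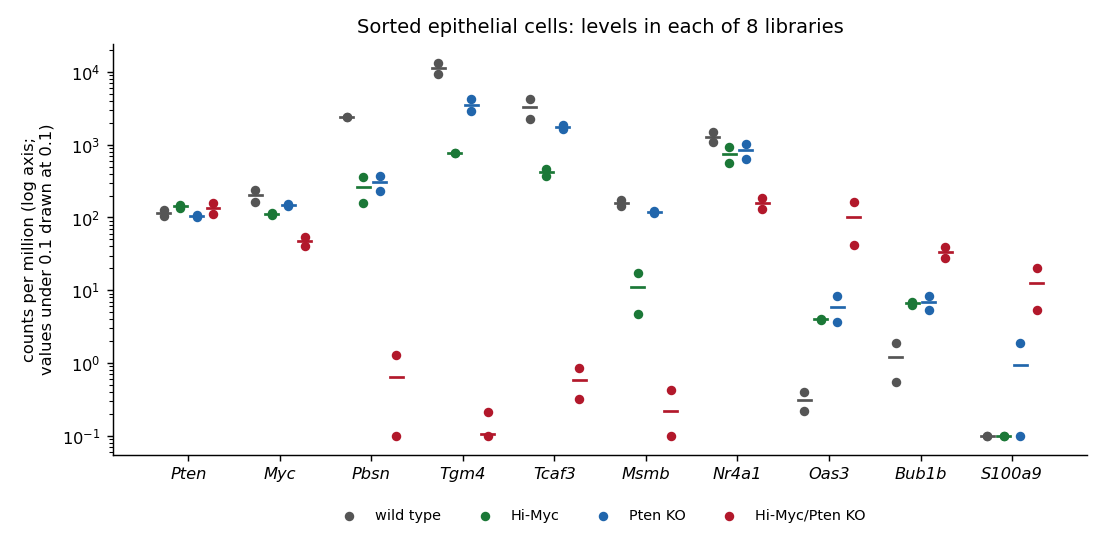
Counts-per-million (log axis) of selected genes in each of the 8 sorted epithelial libraries, with each point 1 library and values under 0.1 drawn at 0.1. Tgm4 lies near 11300 CPM in wild type and near 0.106 CPM in Hi-Myc/Pten KO.

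Hi-Myc cells were compared with wild-type cells to ask what the transgene alone changes. Wfdc12, a protease inhibitor of the whey acidic protein family (chromosome 2, 164189231 to 164190608), rose from 0.613 ± 0.557 to 5020 ± 1000 CPM (SD, n = 2), a log2 change of 12.94 ± 1.34 (SE, adjusted p = 0.0408). Lpl, which encodes lipoprotein lipase, rose from 22.3 to 300 CPM (log2 change 3.75 ± 0.40), and the drug-metabolising oxidase Fmo3 rose by 5.91 ± 0.46. Tgm4, a transglutaminase secreted by luminal cells (chromosome 9, 123034726 to 123067561), fell from 11300 ± 2880 to 767 ± 8.30 CPM (-3.88 ± 0.46, adjusted p = 0.0429). Prdx6, a peroxiredoxin, fell from 2640 to 357 CPM (-2.89 ± 0.25), and Ahr, the aryl hydrocarbon receptor, changed by -1.98 ± 0.22. Both libraries of 1 genotype lay above both of the other in these genes, as the rule for named genes required. Without 1 of the wild-type or Hi-Myc libraries each of them lost its call, where such a fit rests on 1 library in a genotype. In all, 23 genes were called, 14 higher and 9 lower, where 2948 passed an unadjusted p of 0.05 and DESeq2 called 967. Scaling by library totals moved the higher share of calls from 60.9% to 76.7%.

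Among the lists in Hi-Myc cells, 22 of 37 cell cycle genes were higher when adjusted over the list alone, with a median log2 change of 1.05. The list stood above other genes at a camera adjusted p of 6.82e-16, and at adjusted p = 0.441 with an estimated correlation. The interferon response had 18 of 30 genes higher when adjusted over the list alone, with Ifi27 called over all genes (1.92 ± 0.22, adjusted p = 0.0429). Its median was 1.92 (camera adjusted p = 1.74e-10; adjusted p = 0.686 with an estimated correlation). Ribosome biogenesis and MYC targets had a median of 0.39 and 4 of 41 genes higher when adjusted over the list alone (camera adjusted p = 3.2e-05; adjusted p = 0.698 with an estimated correlation). Npm1 of that list stood at 1.21 ± 0.25. In the androgen-regulated luminal list 8 of 22 genes were lower when adjusted over the list alone, and Tgm4 was the member called over all genes. Its median was -0.76 (camera adjusted p = 0.000677; adjusted p = 0.467 with an estimated correlation). Of 15 basal genes 3 were lower when adjusted over the list alone, and Krt14 stood at -3.37 ± 0.47 with an adjusted p of 0.0591. The basal median was -1.20 (camera adjusted p = 3.2e-05; adjusted p = 0.686 with an estimated correlation). Mitochondrially encoded genes (median 3.05), leukocyte genes (1.41), fibroblast and smooth muscle genes (1.24) and oxidative phosphorylation (0.27) stood higher and FOXO targets (-0.35) lower. Their camera adjusted p-values were 8.48e-06, 0.000434, 0.0099, 0.00594 and 0.0287, and they had adjusted p-values of 0.686, 0.686, 0.698, 0.709 and 0.467 with an estimated correlation. The median, mean and test direction differed in sign for 3 uncalled lists. They were 0.0115, -0.0107 and down for MHC class I, 0.269, -0.0301 and up for MHC class II, and 0.0241, -0.0263 and up for glycolysis. Without wild-type replicate 1 or 2 or Hi-Myc replicate 1 or 2 the count of called genes was 0 and Ifi27 was at adjusted p-values of 0.0956 to 0.263, where those fits rest on 1 library in a genotype. It was 1 (Fmo3) without Pten KO replicate 1 or 2, 587 without Hi-Myc/Pten KO replicate 1 and 554 without replicate 2.

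Pten KO cells were compared with wild-type cells to ask what loss of Pten alone changes. Of 37 cell cycle genes, 26 were higher when adjusted over the list alone, with a median log2 change of 1.23 (camera adjusted p = 3.73e-27; adjusted p = 0.173 with an estimated correlation). Mcm2, of the replicative helicase, stood at 0.59 ± 0.18. Genes of the leukocyte list had a median of 1.77, those of the interferon response 0.89 and those of cholesterol and fatty acid synthesis 0.42. Their camera adjusted p-values were 3.02e-07, 3.27e-05 and 3.27e-05, each at adjusted p = 0.754 with an estimated correlation. Single genes of these lists were Lyz2, a lysozyme of myeloid cells, at 1.77 ± 0.48, Isg15 at 1.67 ± 0.64 and Fasn, the fatty acid synthase, at 1.29 ± 0.28. The luminal progenitor list had a median of 0.56 with Ly6a at 2.01 ± 0.41 and Clu at 1.70 ± 0.53 (camera adjusted p = 0.0163; adjusted p = 0.754 with an estimated correlation). Chemokines (median 0.23) and MHC class I (0.43) also stood higher at camera adjusted p-values of 0.0106 and 0.0163, and p53 targets had a median of 0.0171 at 0.0489. Seminal vesicle genes (median -1.79), immediate early genes (-0.36), ribosome biogenesis (-0.17), endothelial genes (-0.65) and erythrocyte genes (-2.53) stood lower. Their camera adjusted p-values were 0.0112, 0.0163, 0.0163, 0.0186 and 0.0186. With an estimated correlation each of these 8 lists was at adjusted p = 0.754.

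Over all genes, edgeR called 0 genes in Pten KO against wild type, where 1114 had an unadjusted p under 0.05, the smallest adjusted p was 0.0551 and DESeq2 called 144. That smallest value was for Apobr, a receptor for lipoproteins, which was singled out after its values were seen. It had 3.45 ± 0.39 CPM in wild type and 42.5 ± 0.25 in Pten KO, a log2 change of 3.62 ± 0.29. Apobr was the 1 gene called without Hi-Myc/Pten KO replicate 1 (adjusted p = 0.0123) or without replicate 2 (0.0141). Tgm4 stood at -1.67 ± 0.42 with an adjusted p of 0.457. The median, mean and test direction differed in sign for the uncalled basal list (0.209, 0.0569 and down), senescence list (-0.0909, 0.128 and up), neuroendocrine list (-0.049, 0.526 and up) and oxidative phosphorylation (0.00222, -0.0148 and down).

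Hi-Myc/Pten KO cells were compared with wild-type cells to ask what both lesions change together. Among the largest falls were genes of luminal secretion. Tgm4 fell from 11300 ± 2880 to 0.106 ± 0.15 CPM, which is 2 counts in all and a ratio of 93200 (counting interval 25800 to 769000). Pbsn, which encodes probasin (chromosome X, 77837901 to 77853623), fell from 2400 ± 4.81 to 0.651 ± 0.921 CPM (log2 change -11.97 ± 1.20, n = 2 and 2). Tcaf3, a regulator of TRP channels (chromosome 6, 42584866 to 42597692), fell from 3250 ± 1360 to 0.593 ± 0.389 CPM (-12.45 ± 0.64, adjusted p = 0.00115). Msmb, a secreted microseminoprotein, fell 859-fold to 3 counts (interval 294 to 4170). Otol1 and Cdhr1 rose at least 193-fold and 125-fold, and Acod1, the itaconate-producing enzyme of activated myeloid cells, at least 110-fold, all from 0 counts. In the androgen-regulated luminal list 10 of 22 genes fell and 1 rose, as also when adjusted over the list alone. The median was -1.57 (camera adjusted p = 0.000119; adjusted p = 0.248 with an estimated correlation). In all, 4672 genes were called, 2409 higher and 2263 lower.

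Proliferation, biosynthesis and energy lists rose in Hi-Myc/Pten KO cells. Of 37 cell cycle genes 35 rose, and 37 when adjusted over the list alone, with a median log2 change of 2.74 (camera adjusted p = 1.43e-20; adjusted p = 0.248 with an estimated correlation). Among them Ube2c, of the anaphase-promoting complex pathway, rose by 4.87 ± 0.64 and the spindle checkpoint kinases Bub1b and Bub1 by 4.74 ± 0.55 and 4.67 ± 0.58. Ribosome biogenesis and MYC targets had 19 of 41 genes higher, and 20 higher and 1 lower when adjusted over the list alone, with Cdk4 at 1.79 ± 0.18 and C1qbp at 1.69 ± 0.25. The list's median was 0.62 (camera adjusted p = 4.06e-05; adjusted p = 0.648 with an estimated correlation). In glycolysis 12 of 19 genes rose and Pfkfb3 fell, with 14 higher and 1 lower when adjusted over the list alone. Its median was 1.66 (camera adjusted p = 8.79e-05; adjusted p = 0.532 with an estimated correlation). The enolase gene Eno1 rose from 41.7 ± 4.95 to 336 ± 104 CPM (3.01 ± 0.27), and the lactate transporter Slc16a3 by 2.90 ± 0.39. Oxidative phosphorylation had 17 of 25 genes higher, 20 when adjusted over the list alone, and a median of 0.82 (camera adjusted p = 4.76e-06; adjusted p = 0.573 with an estimated correlation). In polyamine and one-carbon metabolism 6 of 17 rose and 2 fell, 8 and 2 when adjusted over the list alone, and the folate enzymes Tyms and Mthfd1l rose by 2.44 ± 0.24 and 2.25 ± 0.33. The median was 0.93 (camera adjusted p = 0.0294; adjusted p = 0.512 with an estimated correlation).

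Some immune-related lists rose in the same sorted cells, while the checkpoint and suppression list and the MHC class II list were not called. The interferon response had 25 of 30 genes higher, 27 when adjusted over the list alone, and a median log2 change of 4.10 (camera adjusted p = 2.66e-12; adjusted p = 0.512 with an estimated correlation). The antiviral genes Oas3, Zbp1 and Ifi44 rose by 8.28 ± 0.95, 6.92 ± 0.82 and 6.68 ± 0.87. Of 36 chemokine and cytokine genes 16 rose and 4 fell, 17 and 4 when adjusted over the list alone, with a median of 1.95 (camera adjusted p = 0.00123; adjusted p = 0.512 with an estimated correlation). Cxcl5, a neutrophil attractant (chromosome 5, 90759360 to 90761624), rose from 0.214 ± 0.161 to 84.1 ± 12.5 CPM (8.55 ± 0.79), and Cxcl3 rose at least 79.2-fold from 0 counts. In MHC class I presentation 9 of 18 rose and 1 fell, 10 and 1 when adjusted over the list alone, with Psmb8 at 2.73 ± 0.51. The median was 1.19 (camera adjusted p = 0.0174; adjusted p = 0.741 with an estimated correlation). Of 14 measured checkpoint and suppression genes 3 rose and 2 fell, 4 and 2 when adjusted over the list alone (camera adjusted p = 0.0981). Among them was Arg1, the arginine-degrading enzyme, which rose from 1.71 to 137 CPM (6.3 ± 0.63). Leukocyte genes had 8 of 20 higher and 1 lower, also when adjusted over the list alone, and a median of 1.65 (camera adjusted p = 0.00322; adjusted p = 0.532 with an estimated correlation). S100a9 was at least 81.3-fold higher from 0 counts and Cd3e lower by a ratio of 77.9 (interval 13.6 to 3110). Fibroblast and smooth muscle genes had 6 of 15 higher, 7 when adjusted over the list alone, with Col3a1 rising from 488 to 3090 CPM. Their median was 1.87 (camera adjusted p = 0.027; adjusted p = 0.693 with an estimated correlation). Without wild-type replicate 1 or 2 the calls ended for Psmb8 (adjusted p = 0.058 and 0.0677), S100a9 (0.13 and 0.117) and Col3a1 (0.152 and 0.0643). Leaving out Hi-Myc/Pten KO replicate 1 put S100a9 at 0.0788 and Col3a1 at 0.0966, and leaving out Pten KO replicate 1 or 2 put Col3a1 at 0.0521 or 0.0525.

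Stress and feedback lists fell in Hi-Myc/Pten KO cells. Of 18 immediate early genes 15 fell, 17 when adjusted over the list alone, with a median of -2.04 (camera adjusted p = 2.46e-08; adjusted p = 0.248 with an estimated correlation). Nr4a1, a nuclear receptor induced within minutes of stimulation, fell from 1290 ± 301 to 158 ± 39.5 CPM (-3.03 ± 0.40). In the unfolded protein response 7 of 16 fell, 8 when adjusted over the list alone, with the chaperone gene Hspa5 at -1.71 ± 0.38. Hspa5 lost its call without wild-type replicate 1 (adjusted p = 0.0775) or 2 (0.0679) or Hi-Myc/Pten KO replicate 2 (0.056). The median was -0.80 (camera adjusted p = 0.00343; adjusted p = 0.693 with an estimated correlation). Of 16 FOXO targets 5 fell, also when adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.00986; adjusted p = 0.248 with an estimated correlation). Irs2 and Insr of insulin signalling changed by -2.94 ± 0.50 and -1.37 ± 0.15. The senescence list was mixed, with 11 of 31 higher and 4 lower, 12 and 5 when adjusted over the list alone, and a median of 1.13 (camera adjusted p = 0.107). In it Cdkn2a (chromosome 4, 89274471 to 89294653) rose from 0.105 ± 0.00614 to 13.2 ± 3.96 CPM, a ratio of 130 (interval 35.6 to 1080). The cell cycle inhibitor p16 is 1 product of this gene, and a count over the whole gene cannot say which product rose.

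The remaining lists of this comparison were not called. In camera the adjusted p was 0.425 for luminal progenitor (5 of 19 higher, 2 lower), 0.554 for basal (2 and 2 of 15, Krt5 at 2.45 ± 0.50), 0.377 for endothelial and 0.833 for erythrocyte genes. It was 0.96 for p53 target (2 and 3 of 21), 0.242 for EMT (4 of 23 higher, Fn1 at 2.84 ± 0.40), 0.435 for cholesterol (4 of 24 higher, Dhcr7 at 1.59 ± 0.27) and 0.133 for mitochondrially encoded genes. The median, mean and test direction differed in sign for seminal vesicle genes (0.411, -0.807 and down at 0.0981, 2 of 11 lower), MHC class II (-0.113, 0.143 and down at 0.96, 1 of 8 higher) and neuroendocrine genes (0.141, -0.392 and up at 0.96). Of the neuroendocrine genes Stmn1 rose by 1.67 ± 0.22 and Chga fell by 4.43 ± 0.97. Placing genes with 0 counts at their bound moved no list median in the 5 comparisons between genotypes. The count of 4672 became 1056 without wild-type replicate 1 and 1668 without replicate 2, and 52 and 58 of the 101 named genes called kept the call. Krt5 lost the call without wild-type replicate 1 or 2 (adjusted p = 0.0772 and 0.0825), Chga without replicate 1 (0.0775) and Dhcr7 without replicate 2 (0.0521).

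**Figure D2:**
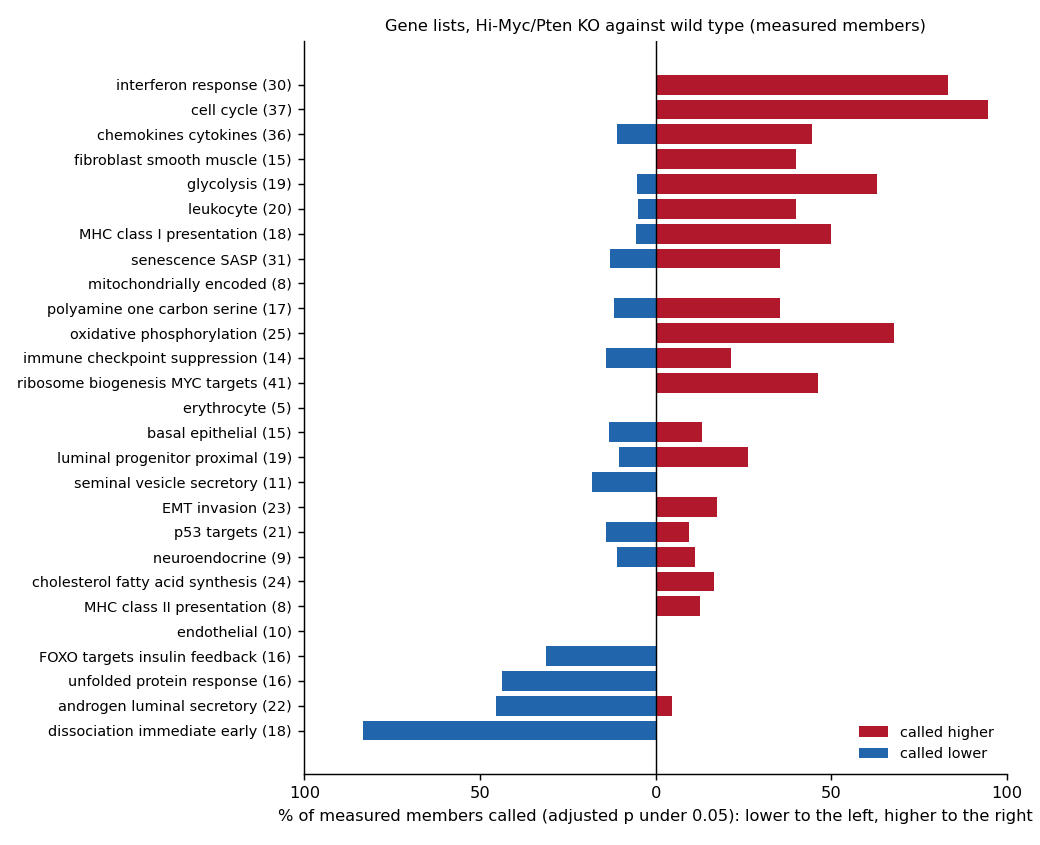
Percent of the measured members of each list called lower (left) or higher (right) in Hi-Myc/Pten KO against wild type, at an adjusted p under 0.05, with lists ordered by median log2 fold change. The bar of the cell cycle list stands for 35 of 37 genes higher and that of the immediate early list for 15 of 18 lower.

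Hi-Myc/Pten KO cells were compared with Pten KO cells to ask what the transgene adds where Pten is lost. Tcaf3 fell from 1750 ± 174 to 0.593 ± 0.389 CPM (log2 change -11.56 ± 0.63, adjusted p = 0.00164, n = 2 and 2). Pbsn fell by 8.98 ± 1.10, and Tgm4 fell to 2 counts, a ratio of 28300 (interval 7840 to 234000). Cdkn2a rose by 4.75 ± 0.60, and Ctxn3 rose at least 216-fold from 0 counts. The stress chaperone gene Hspb1 fell by 2.52 ± 0.35. Of 37 cell cycle genes 29 rose, 34 when adjusted over the list alone (median 1.68, camera adjusted p = 9.36e-14; adjusted p = 0.276 with an estimated correlation). Of 41 ribosome biogenesis genes and MYC targets 22 rose, 25 when adjusted over the list alone, Npm1 by 1.99 ± 0.26 (median 0.84, camera adjusted p = 3.2e-08; adjusted p = 0.513 with an estimated correlation). Of 30 interferon genes 24 rose, 26 when adjusted over the list alone (median 3.09, camera adjusted p = 2.59e-11; adjusted p = 0.513 with an estimated correlation), with Isg15 at 4.80 ± 0.67. Oxidative phosphorylation had 15 of 25 higher, 20 when adjusted over the list alone (median 0.85, camera adjusted p = 6.6e-07; adjusted p = 0.513 with an estimated correlation). Glycolysis had 14 of 19 higher and 1 lower, also when adjusted over the list alone (median 1.37, camera adjusted p = 0.000123; adjusted p = 0.513 with an estimated correlation). Androgen-regulated genes had 10 of 22 lower and 1 higher, 12 and 1 when adjusted over the list alone (median -1.38, camera adjusted p = 1.3e-05). Immediate early genes had 11 of 18 lower, 14 when adjusted over the list alone (-1.26, 1.78e-07), and FOXO targets 4 of 16 lower (-0.46, 0.0104). These 3 lists were at adjusted p = 0.276 with an estimated correlation. Without Pten KO replicate 1 or 2, Isg15 was at adjusted p-values of 0.056 and 0.0626, Npm1 at 0.0542 and 0.0725 and Ctxn3 at 0.0511 and 0.0633.

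Smaller shifts in this comparison were a median of 0.87 for polyamine metabolism (5 of 17 higher, camera adjusted p = 0.00173) and 0.83 for checkpoint genes (2 of 14 higher, 0.0197), both at adjusted p = 0.298 with an estimated correlation. The checkpoint genes that rose were Arg1 by 3.53 ± 0.53 and Lgals9, which encodes a galectin, by 3.13 ± 0.43. Chemokines had 11 of 36 higher and a median of 1.00 (0.0104; adjusted p = 0.513 with an estimated correlation). The unfolded protein response had a median of -1.09 (8 of 16 lower, 0.00168) and mitochondrially encoded genes one of 1.68 (0.0328), both at adjusted p = 0.65 with an estimated correlation. Fibroblast genes had a median of 1.74 (3 of 15 higher, 0.00782; adjusted p = 0.608 with an estimated correlation). The median, mean and test direction differed in sign for the luminal progenitor list (0.174, -0.0933 and down), the neuroendocrine list (0.127, -0.918 and down) and the seminal vesicle list (2.2, 2.64 and down), none of them called. In all, 3910 genes were called, 1911 higher and 1999 lower. The count became 442 without Pten KO replicate 1 and 174 without replicate 2. Without replicate 1 Arg1 was at an adjusted p of 0.0537 and Lgals9 at 0.0505. Of the 89 named genes called, 10 were called whichever library was left out, Cdkn2a, Hspb1, Tcaf3, Pbsn and Tgm4 among them.

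Hi-Myc/Pten KO cells were compared with Hi-Myc cells to ask what loss of Pten adds to the transgene. The keratin gene Krt14 of basal cells (chromosome 11, 100203162 to 100207548) rose from 31.2 ± 3.92 to 1100 ± 332 CPM (log2 change 5.14 ± 0.51, adjusted p = 0.011, n = 2 and 2), and Krt5 rose by 3.93 ± 0.53. Of 15 basal genes 5 rose, and 8 were higher and 1 lower when adjusted over the list alone (median 1.85, camera adjusted p = 0.000578; adjusted p = 0.656 with an estimated correlation). The desmosome genes Dsg3 and Dsc3 rose by 7.70 ± 0.88 and 7.56 ± 0.90. Nkx2-6, a homeobox gene (chromosome 14, 69171802 to 69175518), fell from 56.0 ± 8.98 to 0.719 ± 0.416 CPM (-6.32 ± 0.44). Pdia2 changed by -6.90 ± 0.67 and Tcaf3 by -9.51 ± 0.59. Cxcl5 and Arg1 rose by 5.68 ± 0.66 and 5.90 ± 0.64. Without Hi-Myc replicate 1 the calls ended for Krt14 (adjusted p = 0.0713), Krt5 (0.093), Dsg3 (0.0589), Dsc3 (0.0857) and Arg1 (0.0733). Of 37 cell cycle genes 26 rose, 31 when adjusted over the list alone (median 1.72, camera adjusted p = 2.28e-17; adjusted p = 0.38 with an estimated correlation). Of 19 glycolysis genes 10 rose and 1 fell, 14 and 2 when adjusted over the list alone (median 1.48, 1.93e-06; adjusted p = 0.598 with an estimated correlation). Of 30 interferon genes 14 rose, 22 when adjusted over the list alone (median 2.29, 5.95e-09; adjusted p = 0.644 with an estimated correlation). Immediate early genes had 11 of 18 lower, 16 when adjusted over the list alone (median -1.85, 1.39e-08; adjusted p = 0.432 with an estimated correlation). Androgen-regulated genes had 9 of 22 lower and 1 higher, 12 and 2 when adjusted over the list alone (median -1.01, 0.00236; adjusted p = 0.479 with an estimated correlation).

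Chemokines in this comparison had 8 of 36 higher and 2 lower (median 1.45, camera adjusted p = 0.00236) and polyamine metabolism 3 of 17 higher and 1 lower (0.52, 0.0111), both at adjusted p = 0.598 with an estimated correlation. MHC class I had 2 of 18 higher, Psme2 and Tap2 (median 1.30, 0.000578), and oxidative phosphorylation 1 of 25, Uqcrc1 (0.47, 9.49e-05). Mitochondrially encoded genes had a median of -1.87 (0.0111), and these 3 lists were each at adjusted p = 0.656 with an estimated correlation. The luminal progenitor list had 4 of 19 higher (median 1.21, 0.0267; adjusted p = 0.66 with an estimated correlation). Cholesterol synthesis had Nsdhl and Dhcr7 higher (0.385, 0.0127; adjusted p = 0.698 with an estimated correlation). Ribosome biogenesis had a median of 0.26 and the unfolded protein response one of -0.44, both at 0.0227 and at adjusted p = 0.71 with an estimated correlation. The median, mean and test direction differed in sign for the uncalled leukocyte list (-0.171, 0.347 and up), MHC class II (-0.348, 0.173 and down) and seminal vesicle genes (0.606, 0.745 and down). In all, 1497 genes were called, 711 higher and 786 lower. A fit of only the 4 libraries compared called Tcaf3 and Tgm4 alone, and the replicate number as a block left 417 calls. The count was 14 and 372 without Hi-Myc replicate 1 and 2, 339 and 360 without Pten KO replicate 1 and 2, 614 and 646 without wild-type replicate 1 and 2, and 931 without Hi-Myc/Pten KO replicate 2. Cxcl5, Nkx2-6, Pdia2, Tcaf3 and Tgm4 were the 5 of 70 named genes called in each of the 8 fits. Without Hi-Myc replicate 1 Psme2, Tap2, Uqcrc1, Nsdhl and Dhcr7 were at adjusted p-values of 0.116 to 0.253, without Hi-Myc replicate 2 at 0.0568 to 0.112, and the last 4 lost the call without either wild-type library (0.05 to 0.067) or either Pten KO library (0.0799 to 0.0939). Nsdhl (0.0821) and Dhcr7 (0.0654) lost it without Hi-Myc/Pten KO replicate 1 and Tap2 (0.0832) without replicate 2.

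The interaction asked whether the effect of the transgene differed between Pten KO and wild-type backgrounds. It was called in 3 genes, each falling further on the Pten KO background: Tgm4 (-10.80 ± 0.80), Tcaf3 (-8.62 ± 0.67) and Nkx2-6 (-6.69 ± 0.53), each with an adjusted p of 0.017. The Tgm4 estimate depends on the prior count, since Hi-Myc/Pten KO held 2 counts. Nkx2-6 had 107 ± 37.4 CPM in wild type, 56.0 ± 8.98 in Hi-Myc, 137 ± 7.37 in Pten KO and 0.719 ± 0.416 in both. Krt14 stood at 5.47 ± 0.64 (adjusted p = 0.0899), Ldha at 1.83 ± 0.44 (0.223) and Jun at -1.96 ± 0.38 (0.165). Immediate early genes had a median interaction of -1.34 with 10 of 18 lower when adjusted over the list alone (camera adjusted p = 2.3e-07). Polyamine metabolism had one of 0.71 with 2 higher (0.00016) and androgen-regulated genes one of -0.81 with 9 of 22 lower (0.000236), all 3 at adjusted p = 0.365 with an estimated correlation. Glycolysis had a median of 1.26 with 10 of 19 higher when adjusted over the list alone (2.37e-06) and basal genes one of 1.64 with 3 of 15 higher (0.000102). Cell cycle genes stood at 0.38 (0.00222) and leukocyte genes at -2.00 (0.00786), and all 4 were at adjusted p = 0.697 with an estimated correlation. Oxidative phosphorylation (0.50, 5.9e-05), the interferon response (1.06, 6.38e-05), ribosome biogenesis (0.47, 0.000116), the unfolded protein response (-0.71, 0.011), MHC class I (0.765, 0.0239) and mitochondrially encoded genes (-1.28, 0.0482) were at adjusted p = 0.701 with an estimated correlation. Seminal vesicle genes had a median of 2.39, a mean of 4.19 and a direction down, and p53 targets 0.0111, -0.104 and down, both uncalled. An unadjusted p under 0.05 was reached by 2205 genes and DESeq2 called 310, and scaling by library totals shifted the median of all genes to -0.132. Without wild-type replicate 2, either Hi-Myc or either Pten KO library the count was 0 and the 3 genes were at adjusted p-values of 0.0737 to 0.142. It was 3 without wild-type replicate 1, with Wfdc6b in place of Tgm4 (0.0785), and 81 and 13 without Hi-Myc/Pten KO replicate 1 and 2.

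Single cells were compared to ask how the gland's cell types, monocytes above all, differed between genotypes, and no difference between the 4 libraries has a replicate check. Leukocyte clusters held 677 of 5492 cells in wild type (12.3%, interval 11.5 to 13.2) and 1312 of 3843 in Hi-Myc (34.1%, 32.6 to 35.7). They held 2054 of 8492 in Pten KO (24.2%, 23.3 to 25.1) and 1675 of 6092 in Hi-Myc/Pten KO (27.5%, 26.4 to 28.6). Neutrophil-like cells, with the granule proteins S100a8 and S100a9 among their markers, were 0 of 5492 in wild type, which allows up to 0.0546%. They were 0.468% (0.278 to 0.739) in Hi-Myc, 1.25% (1.02 to 1.51) in Pten KO and 11.5% (10.7 to 12.3) in Hi-Myc/Pten KO. Of the 825 cells in that cluster 701 came from the Hi-Myc/Pten KO library, so it can be a feature of that library. At a minimum of 500 detected genes the Pten KO share was 0.0418%. Mononuclear phagocytes were 10.1%, 31.2%, 20.2% and 10.6%. This family takes in 3 unnamed clusters whose leading genes held more markers of another class, each a monocyte or dendritic one. T-like cells were 0.382%, 1.09%, 2.40% and 4.45%, NK-like cells 1.37%, 1.35%, 0.0471% and 0.607%, and fibroblast-like cells 2.24%, 18.6%, 23.4% and 7.04%. These fibroblast shares leave out 2 unnamed clusters, one with 8 of 9 fibroblast markers (0.182%, 0.546%, 3.84% and 5.37% of cells) and one with 5 of 9 (0.437%, 0.651%, 4.45% and 1.00%). Cells were sorted for viability after digestion of the gland, so yield from each type enters these shares. One unnamed cluster of 1515 cells, 1312 of them from Hi-Myc/Pten KO, had a median of 44.3% mitochondrial counts.

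**Figure D3:**
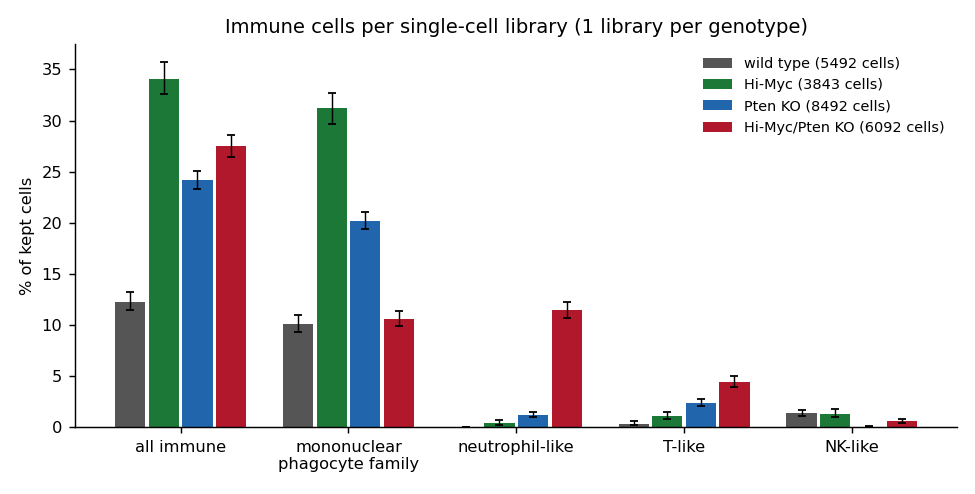
Percent of kept cells in leukocyte clusters and their main classes in each of the 4 single-cell libraries, with exact 95% binomial intervals that cover counting error only. Neutrophil-like cells make up 11.5% of the Hi-Myc/Pten KO library.

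The series names non-classical monocytes and their senescence, so these were looked for by markers fixed beforehand. No cluster met the definition of non-classical or classical monocytes, which leaves out monocytes within other clusters. An unnamed cluster of 644 cells had Ccr2 among its leading genes and 6 of 6 markers of type 2 dendritic cells. The non-classical marker Cx3cr1 was a leading gene of an unnamed cluster of 1080 cells and of the macrophage-like cluster of 1445 cells. The classical marker F13a1 was one of an unnamed cluster of 735 cells. Each of these 3 clusters had 11 of 11 macrophage markers. The authors labelled 314 Hi-Myc cells as monocytes (7.77%, 6.96 to 8.64), and these had 6 of 6 migratory dendritic, 7 of 9 neutrophil and 2 of 11 non-classical monocyte markers. Of these cells 94.9% fell in the mononuclear phagocyte family and 5.1% in the neutrophil-like cluster. Per cell, 6 of the 11 non-classical monocyte markers were searched (Ace, Treml4, Spn, Eno3, Adgre4 and Cd300e). Cx3cr1, Nr4a1, Gngt2, Itgal and Pglyrp1 were left out. This search, its choice of genes and its minimum of 2 were not among the tests fixed beforehand. Leukocytes with at least 2 of the 6 searched genes were 1.77%, 0.534%, 0.73% and 0.716% in wild type, Hi-Myc, Pten KO and Hi-Myc/Pten KO. Among mononuclear phagocytes alone, which leaves out neutrophil-like cells, the shares were 1.62%, 0.584%, 0.757% and 1.39% (0.637 to 2.62 in Hi-Myc/Pten KO). Cells labelled epithelial, which should lack these genes, had 0.96%, 0.473%, 0.529% and 0.134%. The authors labelled 113 cells of the Pten KO library (1.20%, 0.989 to 1.44) and 761 of the Hi-Myc/Pten KO library (11.5%, 10.7 to 12.3) as MDSC in the cell type column of each library, and no cells of the other libraries. A further column, over all libraries, also labels 17 Hi-Myc cells as MDSC (0.421%, 0.245 to 0.673), which had 9 of 9 neutrophil markers. The 113 Pten KO cells expressed 9 of 9 neutrophil markers and 4 of 11 non-classical monocyte markers. Of the 105 not marked as doublets, 100% fell in the neutrophil-like cluster. In Hi-Myc/Pten KO, 99.4% of the 698 labelled cells not marked as doublets fell in the neutrophil-like cluster, and the 761 cells expressed 9 of 9 neutrophil markers and 5 of 11 non-classical monocyte markers. They held S100a9 at 46100 CPM, Csf3r at 785, Cxcr2 at 460 and Ly6g at 112, where mononuclear phagocytes of the same library held 51.3, 25.7, 0.968 and 0. The monocyte and macrophage genes Csf1r, Cx3cr1, Ccr2 and C1qa were at 34.9, 2.05, 2.74 and 14.4 CPM in cells labelled MDSC and at 401, 311, 384 and 3040 in mononuclear phagocytes. At least 1 molecule of S100a9 was seen in 87.3% of cells labelled MDSC (median 1884 counts) and in 19.0% of cells labelled epithelial.

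**Figure D4:**
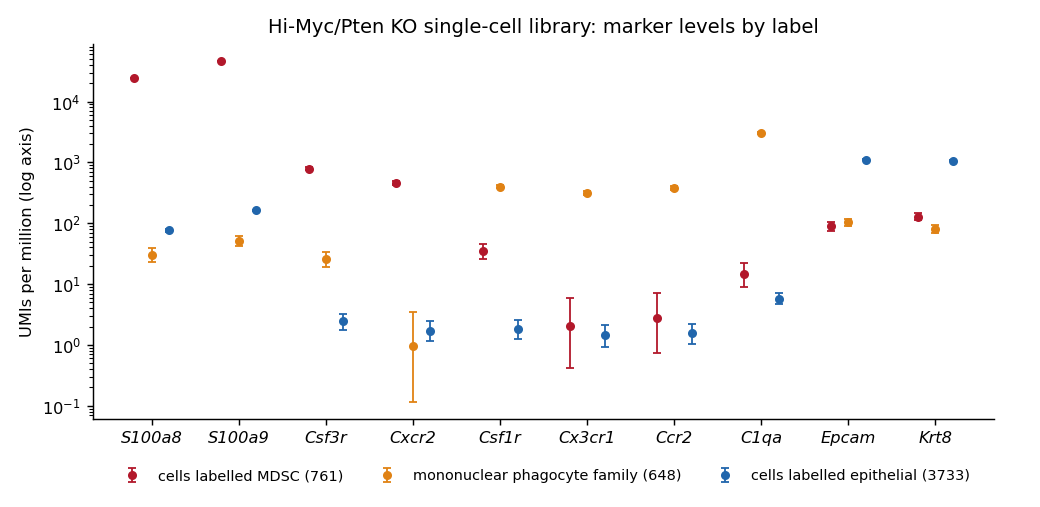
Molecules-per-million (log axis) of neutrophil and monocyte markers in the Hi-Myc/Pten KO single-cell library, for 761 cells labelled MDSC, 648 mononuclear phagocytes and 3733 cells labelled epithelial, with exact 95% Poisson intervals. S100a9 stands at 46100 in cells labelled MDSC and 51.3 in mononuclear phagocytes.

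Among senescence genes in these cells was Cdkn1a, which encodes the cell cycle inhibitor p21. Cells labelled MDSC had 830 CPM of Cdkn1a in Hi-Myc/Pten KO (interval 783 to 878) and 363 in Pten KO (250 to 510), a ratio of 2.28 (1.62 to 3.33), where T cells of the same libraries had 48.6 and 23.1 CPM. A molecule of Cdkn1a was found in 42.2% of them in Hi-Myc/Pten KO and 13.3% in Pten KO at median counts of 1884 and 771.5. After thinning every cell to 500 counts it was found in 23.8% (20.8 to 27) and 11.5% (6.27 to 18.9), with no cell left out. T cells of Hi-Myc/Pten KO, at a median of 1326 counts, had 6.29% before and 3.14% (1.58 to 5.55) after thinning. Those of Pten KO, at a median of 2328 counts, had 5.03% and 0.559% (0.0141 to 3.07). Of the authors' 4 monocyte clusters within these 761 cells, cluster 3 (163 cells, also labelled senescent monocytes) had the most Cdkn1a, at 1550 CPM and 41.7% of cells after thinning. The values were 438 CPM and 15.4%, 748 and 21%, and 718 and 23.5% in clusters 1, 2 and 4. A further label is named for Cdkn1a, so the labels may rest on that gene. Cxcl2 was 3.02 times (2.83 to 3.23) and Cxcl1 2.56 times (1.95 to 3.42) the Pten KO level in cells labelled MDSC, and Il1b was 0.743 times (0.698 to 0.792). Of 20 measured senescence genes 8 had intervals above 1 and 4 below, with a median log2 ratio of 0.20 at percentile 90.07 of random lists. The interferon list had 22 of 27 above 1 (median 2.70) and glycolysis 13 of 17 (1.55). The named genes with the highest ratios were Cxcl10 (82.1, 14.7 to 3240), Hilpda (73.1, 13.1 to 2890) and Ifit1 (22.1, 8.63 to 81.3).

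In cells labelled epithelial (5002 in wild type, 1692 in Hi-Myc, 4161 in Pten KO and 3733 in Hi-Myc/Pten KO), secretory genes were among the lowest. The labelled cells sat in different clusters, as 64.9% of those kept in wild type and 0.0589% in Hi-Myc/Pten KO were in 3 of the 4 clusters with Pbsn, Tgm4, Tcaf3 or Msmb among their leading genes (7.53% and 0.118% in the other). In Hi-Myc/Pten KO 51.4% were in unnamed clusters (38.2% in the one with 44.3% mitochondrial counts) and 7.18% in the smooth muscle or pericyte cluster. Pbsn was lower by a ratio of 84400 (15100 to 3330000) in Hi-Myc/Pten KO, Tgm4 by 1360 (1150 to 1620) and Tcaf3 by 711 (492 to 1070). The ratio for Pbsn was 157 (141 to 175) in Hi-Myc and 57.8 (55.4 to 60.4) in Pten KO. Free RNA of such genes was present, with Tgm4 at 1310 CPM in wild-type T cells and 719 CPM in wild-type macrophages. Among the highest ratios in Hi-Myc/Pten KO were Ifit3 at 378 (191 to 877), Wfdc12 at 121 (105 to 140) and Cxcl5, at least 1000-fold above 0 counts. Wfdc12 was 1010 times (873 to 1170) the wild-type level in Hi-Myc. In Pten KO the highest were Tff3, a trefoil factor, at 100000 (18000 to 3960000, from 1 molecule), and the antimicrobial lectin gene Reg3b, at least 1450-fold from 0. CPM in single cells were not scaled for composition, so a fall of abundant secretory transcripts raises the CPM of all other genes. The counts of list members above 1 have no share over all genes beside them. Of 28 interferon genes all 28 lay above 1 in Hi-Myc/Pten KO (median log2 ratio 4.87) and in Pten KO (2.57), and 27 in Hi-Myc (3.03). Of 37 cell cycle genes 37, 30 and 33 lay above 1 in Hi-Myc/Pten KO (3.09), Pten KO (1.15) and Hi-Myc (2.26). In the same order 14 of 15 (4.08), 14 of 14 (3.11) and 9 of 12 (1.56) fibroblast and smooth muscle genes lay above 1, and 14 of 15 (2.40), 12 of 14 (0.94) and 12 of 14 (1.35) basal genes. The androgen-regulated list had medians of -1.13, -0.28 and -0.65 in that order, and the unfolded protein response list had 15 of 16 below 1 in Hi-Myc/Pten KO (-1.95). Immediate early genes had a median of -1.28 in Hi-Myc/Pten KO, -0.73 in Pten KO and 0.39 in Hi-Myc. Cdkn2a was 124 times (47.9 to 457) and Igfbp4 12.8 times (10.6 to 15.5) the wild-type level in Hi-Myc/Pten KO, while Cdkn1a was at 61.3 and 59.0 CPM (ratio 1.04, 0.961 to 1.12).

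**Figure D5:**
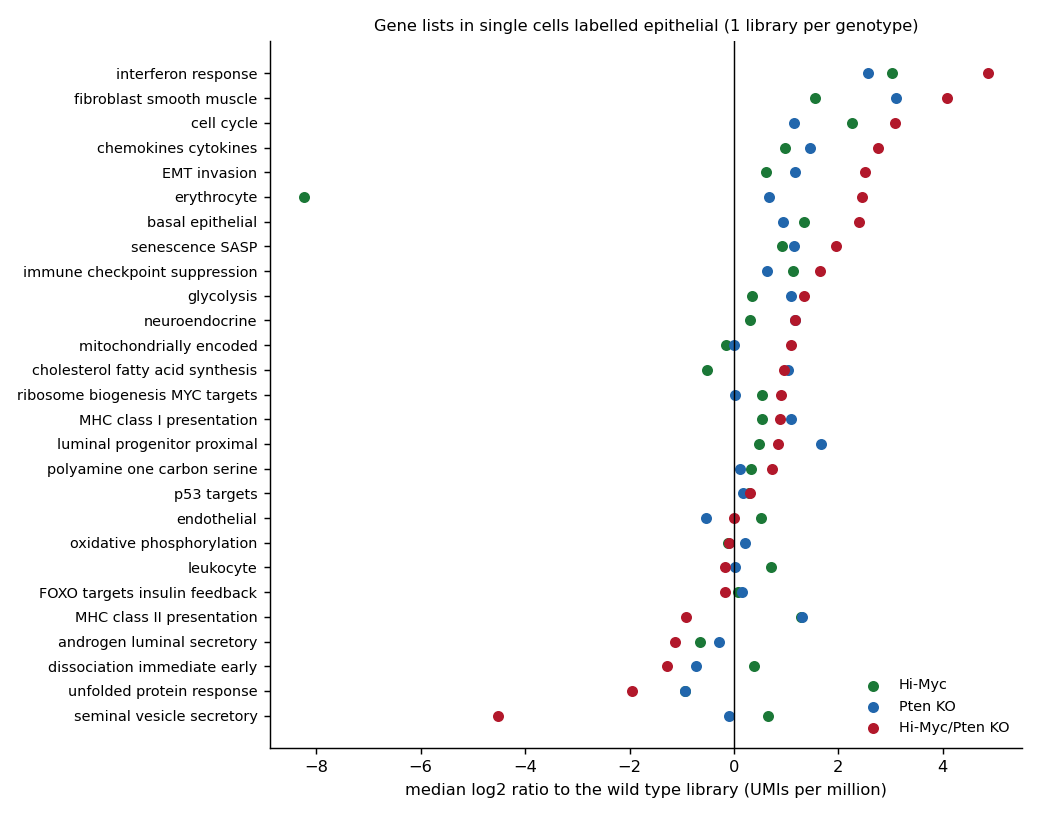
Median log2 ratio to the wild-type library of each gene list in single cells labelled epithelial, for the Hi-Myc, Pten KO and Hi-Myc/Pten KO libraries, 1 per genotype. The interferon list stands highest in Hi-Myc/Pten KO, at 4.87.

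Of the kept cells that the authors labelled macrophages, 93.1% in wild type were in a cluster with Ccl8, Fcna, Retnla and Lyve1 among its leading genes, while 49.4% in Hi-Myc/Pten KO and 89.2% in Pten KO were in one with Spp1 among its leading genes. A further 35.1% in Hi-Myc/Pten KO, and 0.69% in wild type, were in the unnamed cluster of 644 cells, which has 6 of 6 markers of type 2 dendritic cells and the class II gene H2-DMb1 among its leading genes. In those of Hi-Myc/Pten KO Il1b was 317 times (87.4 to 2620) and Spp1, which encodes osteopontin, 494 times (251 to 1140) the wild-type level, while the levels of Retnla, Fcna and Lyve1 were lower by ratios of 20900, 4960 and 1560. In Pten KO macrophages Il1b and Spp1 were 222 and 108 times the wild-type level, and in Hi-Myc macrophages the monocyte attractant Ccl8 was 29.0 times (26.9 to 31.3) and Cxcl2 0.034 times (0.0293 to 0.0393). The MHC class II list had 9 of 9 above 1 in Hi-Myc/Pten KO macrophages (median 1.91), glycolysis 14 of 19 (1.73) and senescence 15 of 25 with 7 below (1.17), with Cdkn1a at 2.1 times (1.75 to 2.52). In cells labelled T, Ctla4, an inhibitory receptor, was 27.1 times (7.32 to 226) the wild-type level in Hi-Myc/Pten KO and the granzyme gene Gzma was lower by a ratio of 368 (178 to 918), while Tgm4 and Pbsn, which free RNA carries into T cells, were also among the lowest. The wild-type cells labelled T matched NK markers best (7 of 7), with 46.7% in the NK and 12.3% in the T cluster, where those of Hi-Myc/Pten KO matched T markers (11 of 11), with 10.7% and 79.4%. Fibroblast-like cells of Hi-Myc/Pten KO had Angpt1 at 273 times and Wif1 at 53.1 times the wild-type level, and Atf3 and Socs3 lower by ratios of 28.3 and 23.6. In wild type 91.1% of them were in 1 cluster that held 11.4% in Hi-Myc/Pten KO, where 70.4% were in another with Angpt1 among its leading genes. Luminal progenitor-like cells, of which 85.3% in Hi-Myc/Pten KO and 10.1% in wild type were in a cluster with Ifit3 among its leading genes, had Cxcl10 at 141 times and Ifit3 at 476 times, and basal-like cells had Isg15 at 55.9 times and Krt13 at 47.6 times the wild-type level.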

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

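The tests on cells labelled MDSC, on immediate early genes and with fibroblast scores as covariates were chosen only after the result was seen, and those of fibroblast and leukocyte RNA in sorted cells were set before. Tgm4, Tcaf3 and Nkx2-6 stand out because the effect of the Hi-Myc transgene differed between the Pten KO and wild-type backgrounds in a test of the difference itself, the interaction in edgeR. The log2 difference was -10.8 for Tgm4, -8.62 for Tcaf3 and -6.69 for Nkx2-6, and the Tgm4 value depends on the prior count, since Hi-Myc/Pten KO held 2 counts. Without wild-type replicate 2, either Hi-Myc library or either Pten KO library these 3 genes were at adjusted p-values of 0.0737 to 0.142, and Tgm4 was at 0.0785 without wild-type replicate 1. No explanation was tested for them, and lower expression within luminal cells and fewer luminal cells among the sorted ones both remain open.

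In sorted Hi-Myc/Pten KO cells 4672 genes were called against wild type (1056 without wild-type replicate 1 and 1668 without replicate 2), and transcripts of fibroblasts and leukocytes, which a sort for EPCAM should remove, were among them (Col3a1 went from 488 to 3090 CPM). RNA of such cells as the source of most genes called higher is argued against by single cells of the Hi-Myc/Pten KO library. Of these genes 8.4% (interval 7.18 to 9.75) had a level in fibroblast-like cells at least 2 times that in cells labelled epithelial, and 13.5% (12.0 to 15.1) had such a level in immune cells, where genes not called had 28.3% and 15.5%. Against this, a covariate of 5 fibroblast genes left 1159 calls and one of the whole fibroblast list 2848, though both scores moved with genotype and cells labelled epithelial may hold RNA of other cells themselves (7.18% were in a smooth muscle or pericyte cluster). Still open are the fibroblast and leukocyte genes among the calls, which either carried-over RNA or the genotype could bring.

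Cells labelled MDSC in the Hi-Myc/Pten KO library held neutrophil transcripts. Free RNA in the droplets is argued against by S100a9, at 285 times (274 to 295) its level in cells labelled epithelial of the same library. Doublets of a neutrophil and another cell stay open for part of the 761 cells, since the markers of 6 other cell types were present at 0.00145 (T) to 0.0374 (luminal progenitor) of their level in those types. These medians summed to 0.0982 (0.0807 to 0.158 over resampled markers), to which free RNA adds, and the 8.28% marked as doublets decide nothing, since the score marked only 330 cells of this library. A hypothesis left by these tests is that most of these cells may be neutrophils or neutrophil-like suppressor cells, though it rests on 1 library and on transcripts alone.

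Immediate early genes were lower in sorted Hi-Myc/Pten KO cells than in wild type (median log2 change -2.04). In single cells their median log2 ratio was -2.77 in fibroblast-like, -2.21 in basal-like and -1.28 in labelled epithelial cells, and -2.03 in labelled macrophages. It was -0.28 in luminal progenitor-like and -0.18 in labelled T cells, and except in basal-like cells the clusters that make up these classes differed between the 2 libraries. Handling or dissociation of the tissue and an effect of genotype cannot be told apart for these genes, because each genotype has 1 single-cell library and no label gives the day or batch of a sample.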

How the results depend on the processing

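The covariates, counts not rounded, shares from the authors' labels and doublets removed from labelled cells were chosen only after the result was seen. Counts of called genes are edgeR's unless DESeq2 is named. They are given in the order Hi-Myc, Pten KO and Hi-Myc/Pten KO against wild type, Hi-Myc/Pten KO against Pten KO and against Hi-Myc, and interaction, which as reported were 23, 0, 4672, 3910, 1497 and 3. Unadjusted p-values under 0.05 numbered 2948, 1114, 7036, 6428, 5010 and 2205, and DESeq2 called 967, 144, 5186, 4467, 2674 and 310. Over all alternatives, 63 of 125 counts stayed within 1.5 times and 62 did not. For those the cause was not tested, apart from the stricter threshold, where the construction is the cause. RLE size factors gave 1 gene (Apobr) for Pten KO, and library totals 193 for Hi-Myc. No filter on low counts gave 88 for Hi-Myc, 1 (Apobr) for Pten KO and 9 for the interaction. An adjusted p under 0.01 gave 0 for Hi-Myc, 1137, 763 and 12 for the 3 comparisons of Hi-Myc/Pten KO, and 0 for the interaction. Fits of the 4 libraries compared gave 39, 8, 1695, 1832 and 2 (Tcaf3 and Tgm4), with no such fit for the interaction. The seminal vesicle score gave 245 for Hi-Myc and 47 for the interaction. The score of 5 fibroblast genes gave 0 for Hi-Myc, 3 for Pten KO (Pigr, Apobr and C1rb), and 1159 and 217 for Hi-Myc/Pten KO against wild type and Pten KO. That of the whole fibroblast list gave 58, 1 (Apobr), 2848, 1495, 2414 and 10. Genes named here with counts of 5 or fewer were chosen after their values were seen. Leaving out each library in turn gave 0 to 587, 0 to 1 (Apobr), 1056 to 4103, 174 to 3385, 14 to 1643 and 0 to 81. The replicate number as a block gave 1 gene for Hi-Myc (Wfdc12), 417 for Hi-Myc/Pten KO against Hi-Myc and 0 for the interaction, and the other 3 counts stayed within 1.5 times. Deviations of same-numbered libraries correlated across genes at -0.282 to 0.164 between genotypes. With 2 libraries per genotype this cannot decide whether the numbers mark a shared animal, litter or day, and no label says so.

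Of 13614 values for 656 named results of bulk genes, 12030 kept their direction and side of the threshold, 1510 no longer passed it and 74 newly passed. An adjusted p under 0.01 ended 194 of these calls, the 5 fibroblast genes 153, the block 94 and DESeq2 1, while DESeq2 added 37. For 162 list results, an estimated correlation ended all 79 calls made at the preset one and added none. Fry ended 48 calls and added 3, no TMM ended 5 and added 3, and the block ended 1. Of 693 ratios in single cells 560 stayed within their interval, 129 moved and 4 reversed. The reversed ratios were Igfbp7 in luminal progenitor-like cells of Hi-Myc/Pten KO (0.903 with doublets kept, 0.782 as a mean over cells), and Cxcl2 (0.796) and Tnf (0.901) in labelled epithelial cells of Hi-Myc as means over cells. The cause was not tested. Of 300 shares 92 moved. Immune shares by the authors' labels were 11.1% in wild type and 23.1% in Pten KO, and 22.0% in Pten KO with at least 500 detected genes. Neutrophil-like shares were 0% in Hi-Myc by the authors' cell type labels (a further column labels 17 cells as MDSC), 0.0418% in Pten KO with at least 500 detected genes and 12.4% in Hi-Myc/Pten KO with doublets kept. Depth and 2 libraries per genotype limit small changes. With 200 changed genes simulated, 2-fold changes were recovered in at most 3.03% of genes and 4-fold ones in 45% to 54%, or 9% for the interaction. These shares can understate recovery in the comparisons of Hi-Myc/Pten KO, where 1497 to 4672 genes were called, since the adjustment is looser when more genes change. False calls were 1.92% (Hi-Myc against wild type) to 10% (interaction) of the simulated calls. The simulation gave each gene the same dispersion in all genotypes, so its rates do not cover unequal spread between them.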

Other observations

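The comparison of sorted cells with single cells below was chosen only after the result was seen. Labelled macrophages of Hi-Myc/Pten KO had 25 of 32 cell cycle genes above the wild-type level and none below (median log2 ratio 1.53), and 11 of 15 checkpoint and suppression genes above and 2 below (1.65). The interferon list had 22 of 28 above in Hi-Myc/Pten KO (1.68), 25 of 28 in Hi-Myc (1.61) and 8 of 26 in Pten KO (0.04). MHC class II genes lay above in 9 of 9 in each of the 3 libraries (1.91, 1.56 and 2.43). The unfolded protein response list had 9 of 13 below in Hi-Myc/Pten KO (-0.80), and 10 of 13 below in both Hi-Myc (-0.85) and Pten KO (-1.05). Cells of Hi-Myc labelled dendritic, which matched macrophage markers best in both libraries (10 of 11), had 23 of 28 interferon genes above (1.92) and 13 of 26 chemokine and cytokine genes below with 4 above (-0.48). In wild type and Hi-Myc 93.1% and 92.2% of the labelled macrophages kept were in 1 cluster, while 89.2% in Pten KO and 49.4% in Hi-Myc/Pten KO were in another. A further 35.1% in Hi-Myc/Pten KO were in a cluster with type 2 dendritic markers and 4.6% in a migratory dendritic one (0.69% and none in wild type), and 3.45% were in a cycling macrophage cluster (0.69%), whose cells had a median of 9999.5 counts. Such cells could bring part of the class II, checkpoint, interferon and cell cycle values, which was not tested. Each of these values compares 1 library with 1 other, and the fibroblast and smooth muscle list also stood higher in macrophages of Pten KO (3.64) and Hi-Myc/Pten KO (2.37).

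A hypothesis was that changes in sorted cells would also be present in single cells labelled epithelial. Of 3933 genes called in sorted Hi-Myc/Pten KO cells against wild type and measured in single cells, 77.9% (76.6 to 79.2) had a single-cell ratio in the same direction. The share was 86.4% of genes called higher, 70.3% of those called lower and 60.7% of genes not called, and the fold changes of called genes had a Spearman coefficient of 0.753 across genes, which are not independent. Against Pten KO 73.9% of called genes and 58.4% of genes not called went the same way. Against Hi-Myc these shares were 76.4% and 58.9%. There the share was 93.3% of genes called higher but 61.4% (57.7 to 65.1) of those called lower. Many of the changes may therefore be shared by labelled epithelial cells of the whole gland. The falls against Hi-Myc are an exception, since their share stood near that of genes not called. Free RNA that differs between the libraries, and labelled cells that fall in different clusters in each, could add to these shares.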
